A study of Mus musculus with 4 samples.

How the data were processed

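Single-cell RNA was measured in 4 libraries of mouse colon cells, 2 per group, made with 10x Genomics 3' chemistry after digestion of colitis tissue, removal of dead cells and magnetic CD45 selection, with 10000 cells processed for each per the labels. The deposited matrices hold counts, that is UMIs per gene and barcode for every barcode including empty droplets, with no normalization. Cell Ranger 6.1.2 and genome build mm10 are credited to the submitters' processing notes. Gene IDs were matched to GENCODE M21 (GRCm38), in which 32235 of 32285 have the same Ensembl ID. Xist gave 54490 or more UMIs in each library and the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty at most 2, so all 4 libraries read as female.

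The libraries held 73289654 and 88754614 UMIs with ECP and 59050508 and 68270824 without. Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs. This gave 10343, 10904, 9032 and 10213 barcodes in the order ECP replicates 1 and 2, then no-ECP replicates 1 and 2. Scrublet, run through scanpy 1.11.5, scored doublets, and the highest scores up to a rate of 0.8% per 1000 barcodes were removed (856, 951, 653 and 834). The median number of genes per kept cell was 1276, 1409, 1285 and 1279.

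Counts scaled to 10000 per cell were log-transformed, and 2000 variable genes ranked within each library gave 30 principal components, with no integration across libraries. A shared neighbour graph (15 neighbours) was clustered by the Leiden method (leidenalg 0.10.2, resolution 1, seed 1) with scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Clusters were named from fixed marker lists: a marker counted where it was found in at least 20% of the cells and at least 2-fold above the rest, a name needed at least 3 markers, and a second class could have at most 0.5 of the markers of the first. These naming thresholds were set after seeing the data, and clusters that met no name were left unnamed.

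For each class with at least 30 cells in every library, the UMIs of its cells were summed per library and compared in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM scaling and a quasi-likelihood test of ECP against no ECP. P-values were adjusted by Benjamini-Hochberg within each class, with a threshold of 0.05, and all cells of a library were compared in the same way. Shares of classes were tested by the same edgeR test on cell counts, with the library total as scale, for classes with at least 10 cells in a library. Gene lists, 30 in number, written before the data were examined along with the comparisons and planned settings, were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01 for lists with at least 5 tested genes. Camera was run again with the correlation estimated from the residuals, and fry was run as another list test. With 2 libraries per group those residuals leave few degrees of freedom. Named genes are the 10 with the largest rise and the 10 with the largest fall in each class among those that passed with all libraries of the groups apart, predicted genes, ribosomal and mitochondrial genes and receptor segments left out; 14 fixed genes; and the 2 up and 2 down with the smallest p of each list. Tnfsf11 is named outside this rule, after its value was seen. A gene with no UMIs in a group is given as a bound against a floor of 3 counts over the group, and one with 1 to 3 counts as a ratio of counts with a 95% counting interval.

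Free RNA was read from barcodes of 50 to 150 UMIs, taken as empty droplets. A gene counts as within reach of free RNA where its level in the class is at most 2 times the level that the class's epithelial transcripts allow free RNA to bring, and as above the empty-droplet level where it exceeds the empty droplets in both libraries of the higher group. Planned settings were DESeq2 size factors, library size alone, the DESeq2 Wald test (DESeq2 1.42.0), no low count filter, a replicate block, each library left out, at least 1000 UMIs, at most 5% mitochondrial UMIs, doublets kept, 5% of UMIs subtracted along the profile of barcodes with 1 to 50 UMIs, thinning to the lowest total, and resolutions 0.5 and 2. Settings chosen after seeing the data were subtraction along the profile of barcodes with 50 to 150 UMIs, subtraction at the share set by epithelial transcripts, the largest cluster of a class alone, fibroblasts without the cluster led by Cxcl13, and T cells or fibroblasts with a cluster otherwise unnamed. Comparisons of neutrophils and dendritic cells, which have 20 to 29 cells in 1 library, and of the T cell cluster led by Foxp3 were also chosen then. Leaving out a library leaves a group of 1, which is assumed to vary like the others.

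Simulated genes had the depth and common dispersion of each sum. By class, 92% to 99% of 4-fold and 26.5% to 79.8% of 2-fold changes were found. The share test, in 50 simulated runs at a preset dispersion of 0.1, found 81% of log2 2 and 96% of log2 3 changes. False calls were 2.44%. Real shares may vary more. Figures were drawn with matplotlib 3.10.9.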

Results

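The comparison asks what a transplant of ECP-treated donor cells changes among gut leukocytes in mouse colitis. Per the labels, C57BL/6 wild-type mice received 3% dextran sulfate sodium, which injures the colon lining, together with an antibody against PD-1, an inhibitory receptor of T cells. In clinical use ECP is short for extracorporeal photopheresis, in which leukocytes are exposed to a photosensitiser and ultraviolet A light; the labels give only the short form. There are 4 single-cell libraries of CD45-selected colon cells, 2 from mice given ECP-treated cells (ECP) and 2 from mice without them (no ECP). After filtering, 9487 and 9953 cells remained with ECP and 8379 and 9379 without (medians 2791, 3047, 2886 and 2863 UMIs per cell). Gene and share p-values measure only the spread between libraries, which may be partly technical. Camera's, at a preset correlation, do not. The labels do not say if a library is 1 mouse.

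Dendritic cells, glia and epithelial cells held larger shares of the ECP libraries and neutrophils smaller ones, and no other class passed. Dendritic cells, which present antigen to T cells, made up 4.29% ± 0.589 against 0.484% ± 0.296 of kept cells, ECP against no ECP (mean ± SD, n = 2 libraries), and rose 8.81-fold (log2 fold change 3.14 ± 0.66, adjusted p = 9.40e-04; edgeR quasi-likelihood test on cell counts, Benjamini-Hochberg). By the same edgeR quasi-likelihood test, enteric glia, the support cells of gut nerves, rose 8.19-fold (1.44% ± 0.657 against 0.175% ± 0.0220; log2 fold change 3.03 ± 0.72, adjusted p = 0.00176), and epithelial cells of the colon lining rose 7.87-fold (17.5% ± 1.92 against 2.23% ± 0.934; log2 fold change 2.98 ± 0.78, adjusted p = 0.00334). Neutrophils, granule-bearing cells of acute inflammation, fell 3.99-fold (0.770% ± 0.672 against 3.08% ± 1.69; edgeR quasi-likelihood test, log2 fold change -1.99 ± 0.63, adjusted p = 0.0119). Macrophages and monocytes (10.5% ± 3.96 against 4.82% ± 0.00920), T cells (10.0% ± 0.811 against 17.2% ± 7.47), B cells (16.9% ± 8.53 against 23.6% ± 21.7), fibroblasts and other stroma (16.2% ± 1.26 against 16.6% ± 7.82) and group 2 innate lymphoid cells (group 2 ILC, 1.67% ± 0.0856 against 2.50% ± 0.549) did not pass. Mast cells and basophils, granule-bearing cells of allergy, did not pass either (0.289% ± 0.0825 against 0.0690% ± 0.0374; log2 fold change 2.06 ± 0.92, adjusted p = 0.0829 by edgeR quasi-likelihood), but passed that edgeR test with TMM scaling over the classes (1.64, adjusted p = 0.0485), at least 1000 UMIs (2.35, adjusted p = 0.00330) and at most 5% mitochondrial UMIs (2.21, adjusted p = 1.60e-04). With 2 libraries a group, an exact permutation test cannot give a 2-sided p below 0.333.

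With a library left out of the edgeR quasi-likelihood test, these shares kept their direction, but calls ended. Such a fit has a group of 1 library and fewer degrees of freedom, so a lost call does not show that 1 library makes the difference. The log2 fold change of dendritic cells was 3.27 without ECP replicate 1, 2.99 without ECP replicate 2 and 3.96 without no_ECP replicate 2. In the same edgeR quasi-likelihood test epithelial cells were at 3.08 without ECP replicate 1 (adjusted p = 0.176) and 2.86 without ECP replicate 2 (adjusted p = 0.193). Enteric glia were at 3.44 without ECP replicate 1 (adjusted p = 0.0931), 2.48 without ECP replicate 2 (adjusted p = 0.193), 3.17 without no_ECP replicate 1 (adjusted p = 0.0575) and 2.91 without no_ECP replicate 2 (adjusted p = 0.102) by edgeR quasi-likelihood. Neutrophils were at -1.30 without ECP replicate 1 (adjusted p = 0.404), -3.38 without ECP replicate 2 (adjusted p = 0.193), -1.29 without no_ECP replicate 1 (adjusted p = 0.269) and -2.47 without no_ECP replicate 2 (adjusted p = 0.102) by edgeR quasi-likelihood. Dendritic cells have no value at resolution 0.5, where no cluster took that name. The neutrophil call of edgeR also ended with TMM scaling over the classes (-2.35, adjusted p = 0.0537), at most 5% mitochondrial UMIs per barcode (-1.95, adjusted p = 0.0741) and immune classes alone in the total (-1.80, adjusted p = 0.278).

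**Figure D1:**
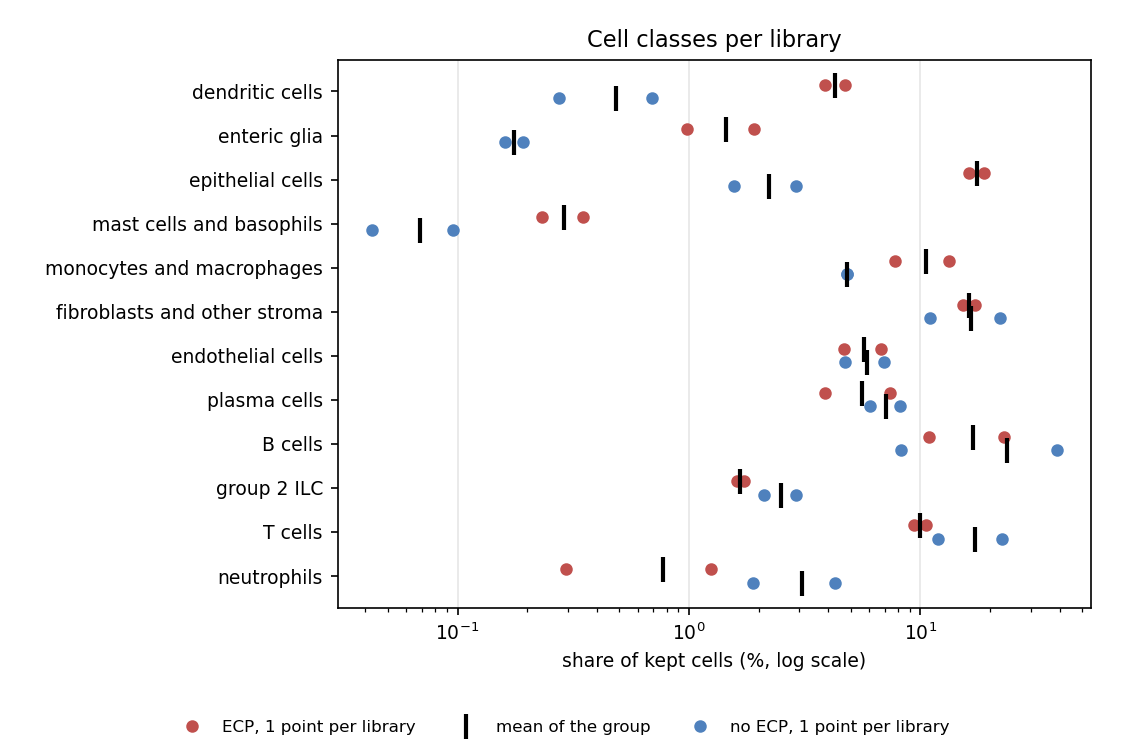
Share of kept cells per class and library on a log scale, with group means. Dendritic cells, enteric glia, epithelial cells and neutrophils passed the test.

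Gene changes below are ECP over no ECP, levels are CPM (counts scaled to the library total), with ± giving the standard error of the log2 fold change, and a gene rose or fell only where it passed the test of its class. In each named gene that rose or fell both ECP libraries lay on 1 side of both others, which chance gives in a share of 0.333 of genes.

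In monocytes and macrophages, the cells that engulf debris and present antigen, some interferon-induced and antigen presentation genes rose while some genes of neutrophil granules fell. Of 9607 tested genes, 259 rose and 85 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 64 of the 259 that rose were within reach of free RNA and 160 lay above the empty-droplet level in both ECP libraries. Retnla, a secreted product of alternatively activated macrophages, rose at least 87.5-fold (80.8 ± 33.8 against 0 ± 0 CPM (mean ± SD, n = 2); adjusted p = 3.96e-04 by edgeR quasi-likelihood). Ifi27l2a and Usp18, both induced by interferon, rose 12.5-fold (log2 fold change 3.64 ± 0.54) and 14.2-fold (log2 3.83 ± 0.62): of the type I interferon list, 12 of the 20 tested members rose, 0 fell and 8 did not pass. Adjusted over the list alone, 17 rose and 0 fell. Camera gave this list an adjusted p = 4.65e-21 (adjusted p = 0.497 with an estimated correlation) at a median log2 fold change of 2.62. Cxcl9, a chemokine that draws T cells, rose 17.7-fold (log2 4.14 ± 0.36) (121 ± 39.4 against 7.46 ± 4.62 CPM (mean ± SD, n = 2); adjusted p = 3.43e-04 by edgeR quasi-likelihood), and Gbp2b, a guanylate-binding protein, rose 5.84-fold (log2 2.55 ± 0.31): of the interferon gamma list, 10 of the 22 tested members rose, 0 fell and 12 did not pass. Camera's adjusted p = 4.22e-12 for this list, or adjusted p = 0.497 with an estimated correlation, and its median log2 fold change was 1.08. Of its members 16 rose and 2 fell adjusted over the list alone. Tap1, the peptide transporter for MHC class I, rose 2.39-fold (log2 1.26 ± 0.21): of the MHC class I list, 6 of the 17 tested members rose, 0 fell and 11 did not pass. The list had 13 up and 0 down adjusted over the list alone. Its camera adjusted p = 2.35e-09, or adjusted p = 0.497 with an estimated correlation, for a median log2 fold change of 0.60. Ciita, the switch of MHC class II transcription, rose 2.18-fold (log2 1.12 ± 0.16) and H2-Aa, a class II chain, 2.40-fold (log2 1.26 ± 0.20): of the MHC class II list, 8 of the 16 tested members rose, 0 fell and 8 did not pass. With a median log2 fold change of 0.58, the list had a camera adjusted p = 2.24e-07 and an adjusted p = 0.497 with an estimated correlation. Alone it gave 8 up and 0 down (adjusted over the list alone). With 5% of the UMIs subtracted along the empty-droplet profile 193 genes changed. In monocytes and macrophages 493 genes changed (296 up) without ECP replicate 2, 185 without no_ECP replicate 1 and 549 without no_ECP replicate 2. Ifi27l2a moved on the log2 scale to 2.97 without ECP replicate 2, 2.98 without no_ECP replicate 1 and 5.08 without no_ECP replicate 2, Usp18 to 2.88 without ECP replicate 2, Cxcl9 to 4.84 without no_ECP replicate 1 and 3.50 without no_ECP replicate 2, Gbp2b to 3.39 without no_ECP replicate 2. In mm10 (GRCm38), Retnla (ENSMUSG00000061100) lies on chromosome 16, 48842551 to 48844461, and Cxcl9 (ENSMUSG00000029417) lies on chromosome 5, 92321347 to 92328079.

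Lcn2, an iron-scavenging granule protein, fell 21.7-fold (log2 -4.44 ± 0.52), and Mmp9, a matrix protease, fell 7.90-fold (log2 -2.98 ± 0.19): of the neutrophil granule list, 0 of the 16 tested members rose, 8 fell and 8 did not pass. The camera adjusted p = 3.17e-28 became adjusted p = 0.30 with an estimated correlation. The median log2 fold change was -1.51, with 0 up and 10 down adjusted over the list alone. Neutrophils, which fell 3.99-fold in share, were not tested as source. Tnf, an inflammatory cytokine, fell 4.58-fold (log2 -2.19 ± 0.39) and Icam1, an adhesion molecule, 1.97-fold (log2 -0.98 ± 0.14): of the NF-kB list, 0 of the 20 tested members rose, 3 fell and 17 did not pass. Its median log2 fold change was -0.21, with 0 up and 6 down adjusted over the list alone. By camera it had an adjusted p = 0.00119 and an adjusted p = 0.497 with an estimated correlation. Cd72, a lectin-like receptor, rose 2.57-fold (log2 1.36 ± 0.20): of the complement and resident macrophage list, 3 of the 17 tested members rose, 0 fell and 14 did not pass. By camera it had an adjusted p = 1.23e-04, and adjusted p = 0.497 with an estimated correlation. The median log2 fold change was 0.44, with 9 up and 1 down adjusted over the list alone. Marco, a scavenger receptor, fell 21.5-fold (log2 -4.43 ± 0.43). Epithelial transcripts rose with them: the colon epithelial list held 0.0979% and 0.144% of the UMIs in the ECP libraries against 0.0311% and 0.0187%, and of its members, among them the goblet cell products Muc2 and Zg16, 13 of the 16 tested members rose, 0 fell and 3 did not pass. The median log2 fold change was 2.96, with 14 up and 0 down adjusted over the list alone. By camera it had an adjusted p = 1.47e-66 and adjusted p = 0.30 with an estimated correlation. Tnf lost its call with the DESeq2 test and with doublets kept. Lcn2 moved on the log2 scale to -3.82 without ECP replicate 1, -7.14 without ECP replicate 2 and -3.85 without no_ECP replicate 1, Tnf to -1.34 without no_ECP replicate 1, Marco to -5.33 without ECP replicate 2. Lcn2 (ENSMUSG00000026822) lies on chromosome 2, 32384633 to 32388252. The macrophage resolution list was not past camera here. Further lists past camera were Th17 and type 3 (up, 3 of 9 members up and 0 down), immunoglobulin secretion and plasma cell (down, 0 of 16 up, 1 down), proliferation (up, 0 of 18 up, 0 down) and tissue dissociation and immediate early (up, 2 of 26 up, 0 down). Their camera test gave an adjusted p = 0.00508 to 0.0294, and adjusted p = 0.497 to 0.570 with an estimated correlation.

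**Figure D2:**
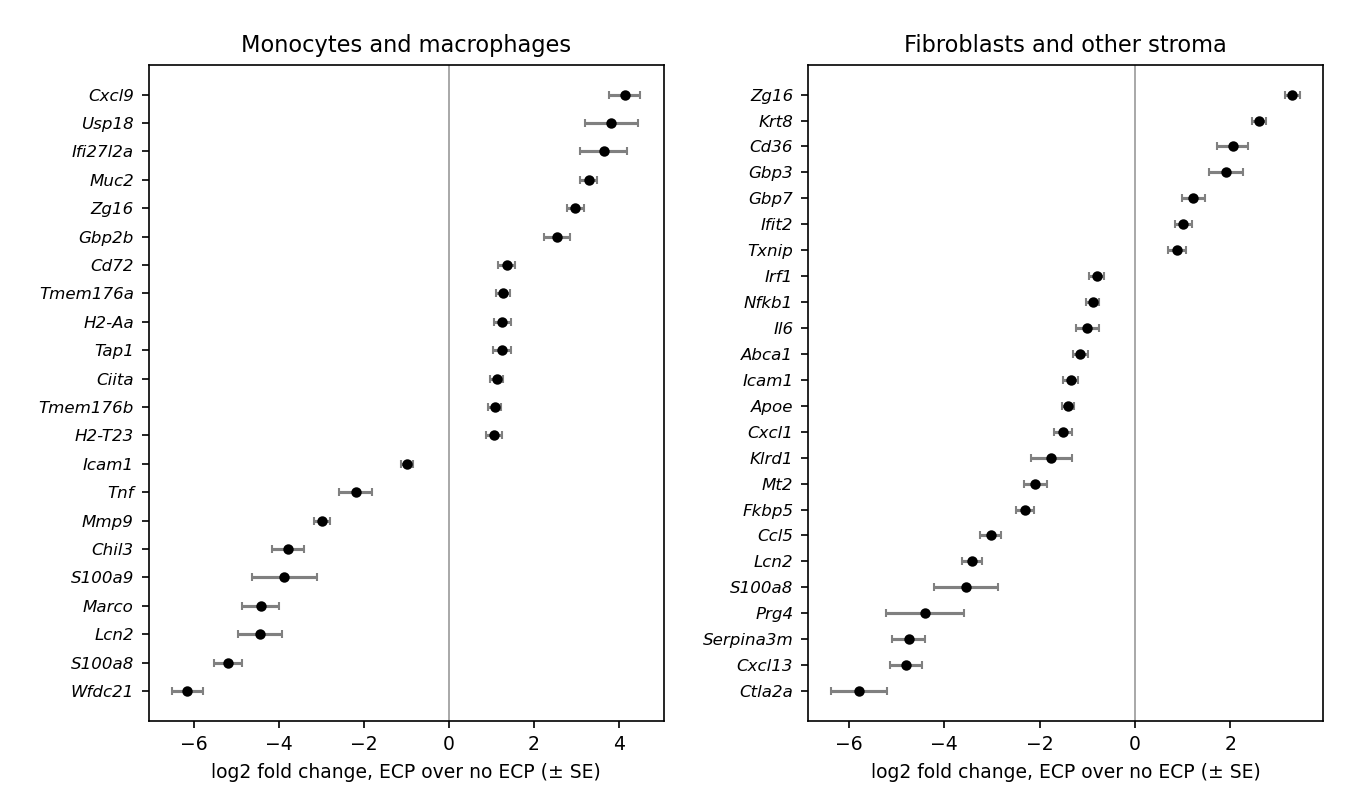
Log2 fold changes with standard errors of called genes in monocytes and macrophages and in fibroblasts and other stroma. Genes given as bounds or ratios of counts are not drawn.

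In fibroblasts, the cells that build connective tissue, some glucocorticoid-induced genes and inflammatory mediators fell, while some interferon-induced genes rose. Of 13126 tested genes, 745 rose and 623 fell by the edgeR quasi-likelihood test; 152 of the 745 that rose were within reach of free RNA and 469 lay above the empty-droplet level in both ECP libraries. The cluster led by Adamdec1 and Igfbp3 held 35.5% and 31.8% of the class in the ECP libraries against 28.6% and 26.3%, the cluster led by C3 and Has1 26.6% and 26.4% against 28.9% and 38.2%, the cluster led by Cxcl13 0.137% and 1.88% against 15% and 13.7%, and the smooth muscle-like cluster led by Myh11 14.9% and 12.8% against 5.72% and 4.92%. Cxcl13, a chemokine for B cells, fell 27.8-fold (log2 -4.80 ± 0.34) (67.4 ± 35.0 against 1884 ± 18.4 CPM (mean ± SD, n = 2); adjusted p = 6.29e-04 by edgeR quasi-likelihood), and its log2 fold change was -3.27 with the cluster it leads left out. Fkbp5, a glucocorticoid-induced co-chaperone, fell 4.92-fold (log2 -2.30 ± 0.19) and Mt2, a metal-binding protein, 4.24-fold (log2 -2.09 ± 0.24): of the glucocorticoid list, 1 of the 15 tested members rose, 10 fell and 4 did not pass. At a median log2 fold change of -0.95, camera gave an adjusted p = 6.99e-08, and adjusted p = 0.602 with an estimated correlation. The list had 2 up and 11 down adjusted over it alone. Oas2, an antiviral enzyme, rose 105-fold by the ratio of counts (95% counting interval 18.3 to 4193): of the type I interferon list, 10 of the 18 tested members rose, 0 fell and 8 did not pass. Adjusted over the list alone, 16 rose and 0 fell. Camera gave this list an adjusted p = 3.78e-09 (adjusted p = 0.815 with an estimated correlation) at a median log2 fold change of 1.58. Of the interferon gamma list, 4 of the 21 tested members rose, 1 fell and 16 did not pass, and Gbp3, a guanylate-binding protein, rose 3.76-fold (log2 1.91 ± 0.35). Camera's adjusted p = 0.0369 for this list, or adjusted p = 0.872 with an estimated correlation, and its median log2 fold change was 0.44. Of its members 6 rose and 2 fell adjusted over the list alone. Icam1, an adhesion molecule, fell 2.55-fold (log2 -1.35 ± 0.15): of the NF-kB list, 0 of the 14 tested members rose, 6 fell and 8 did not pass. The list had 0 up and 7 down adjusted over the list alone. Its camera adjusted p = 2.05e-04, or adjusted p = 0.602 with an estimated correlation, for a median log2 fold change of -0.44. With library size alone as scaling, 865 of 1304 calls were up (66.3% against 54.5%), and in the largest cluster alone 378 genes changed, without Cxcl13 (-0.38) or Icam1 (-1.17, log2 values). In fibroblasts and other stroma 438 genes changed (315 up) without ECP replicate 1 and 515 without ECP replicate 2. Oas2 lost its call without ECP replicate 2. Cxcl13 moved on the log2 scale to -5.45 without ECP replicate 2, Gbp3 to 1.22 without ECP replicate 2. Cxcl13 (ENSMUSG00000023078) lies on chromosome 5, 95956951 to 95961068.

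Cxcl1, which recruits neutrophils, fell 2.84-fold (log2 -1.51 ± 0.20): of the inflammatory chemokine list, 2 of the 14 tested members rose, 4 fell and 8 did not pass. With a median log2 fold change of -0.22, the list had a camera adjusted p = 0.0135 and an adjusted p = 0.817 with an estimated correlation. It gave 2 up and 5 down adjusted over the list alone. Apoe, a lipid carrier, fell 2.64-fold (log2 -1.40 ± 0.13) and Abca1, a cholesterol exporter, 2.21-fold (log2 -1.14 ± 0.16): of the macrophage resolution list, 1 of the 15 tested members rose, 4 fell and 10 did not pass. The camera adjusted p = 0.0307 became adjusted p = 0.602 with an estimated correlation. The median log2 fold change was -0.37, and 2 rose and 4 fell adjusted over the list alone. Lcn2 fell 10.7-fold (log2 -3.41 ± 0.21): of the neutrophil granule list, 0 of the 13 tested members rose, 4 fell and 9 did not pass. Its median log2 fold change was -0.60, with 1 up and 5 down adjusted over the list alone. By camera it had an adjusted p = 0.00138 and an adjusted p = 0.817 with an estimated correlation. Epithelial transcripts held 0.0732% and 0.11% of the UMIs in the ECP libraries against 0.0197% and 0.0152%, and of the colon epithelial list, 16 of the 19 tested members rose, 0 fell and 3 did not pass. By camera it had an adjusted p = 1.75e-60, and adjusted p = 0.503 with an estimated correlation. The median log2 fold change was 2.67, with 18 up and 0 down adjusted over the list alone. In the largest cluster alone Cxcl1 lost its call (-1.41 on the log2 scale). Further lists past camera in fibroblasts were T cell effector and cytotoxic (down, 1 of 9 members up and 2 down) and oxidative phosphorylation (down, 0 of 26 members up and 2 down). Their camera test gave an adjusted p = 0.00525 to 0.0411, and adjusted p = 0.602 to 0.817 with an estimated correlation.

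In endothelial cells, which line blood and lymph vessels, some interferon-induced and immediate early genes rose. The cluster led by Selp and Slco2a1 held 41.1% and 36.7% of the class in the ECP libraries against 52.9% and 53.4%, the cluster led by Flt1 and Podxl 26.2% and 27.4% against 14.2% and 10.6%, and the cluster led by Rgs5 and Flt1 12.4% and 14.6% against 3.92% and 4.98%. The largest cluster alone gave 413 changed genes, 191 of them among the 506 of the class. By the edgeR quasi-likelihood test 374 of 11239 genes rose and 132 fell; 15 of the 374 that rose were within reach of free RNA and 286 lay above the empty-droplet level in both ECP libraries. Rsad2, an antiviral enzyme, rose 7.86-fold (log2 2.97 ± 0.30): of the type I interferon list, 15 of the 17 tested members rose, 0 fell and 2 did not pass. The median log2 fold change was 2.81, with 17 up and 0 down adjusted over the list alone. By camera it had an adjusted p = 1.41e-33 and adjusted p = 0.428 with an estimated correlation. Irgm1, an interferon-induced GTPase, rose 2.32-fold (log2 1.21 ± 0.20): of the interferon gamma list, 9 of the 22 tested members rose, 1 fell and 12 did not pass. At a median log2 fold change of 1.42, camera gave an adjusted p = 3.73e-12, and adjusted p = 0.624 with an estimated correlation. The list had 18 up and 1 down adjusted over it alone. Egr1, a transcription factor of early stimulation, rose 2.79-fold (log2 1.48 ± 0.15): of the dissociation and immediate early list, 8 of the 26 tested members rose, 0 fell and 18 did not pass. Adjusted over the list alone, 17 rose and 0 fell. Camera gave this list an adjusted p = 9.76e-12 (adjusted p = 0.428 with an estimated correlation) at a median log2 fold change of 0.54. Adamdec1, a metalloprotease that also leads fibroblast clusters, rose 24.2-fold (log2 4.6 ± 0.47). Serpina3n, a protease inhibitor with close paralogs, fell 19.0-fold (log2 -4.25 ± 0.31) (7.86 ± 5.45 against 162 ± 21.1 CPM (mean ± SD, n = 2); adjusted p = 0.00266 by edgeR quasi-likelihood). Lcn2 fell 6.76-fold (log2 -2.76 ± 0.19): of the neutrophil granule list, 0 of the 7 tested members rose, 3 fell and 4 did not pass. Camera's adjusted p = 4.73e-06 for this list, or adjusted p = 0.428 with an estimated correlation, and its median log2 fold change was -1.01. Of its members 0 rose and 3 fell adjusted over the list alone. Neutrophils, which fell 3.99-fold in share, were not tested as source. Colon epithelial transcripts made up 0.0932% and 0.148% of the UMIs in the ECP libraries against 0.0504% and 0.0175%, and of that list 7 of the 18 tested members rose, 0 fell and 11 did not pass. The list had 15 up and 0 down adjusted over the list alone. Its camera adjusted p = 6.08e-19, or adjusted p = 0.428 with an estimated correlation, for a median log2 fold change of 1.93. In endothelial cells 171 genes changed without ECP replicate 1, 27 without ECP replicate 2, 1062 without no_ECP replicate 1 and 1458 without no_ECP replicate 2. Irgm1 lost its call without ECP replicate 1 (log2 1.18) or 2 (1.25). Adamdec1 moved on the log2 scale to 4.01 without ECP replicate 2 and 5.57 without no_ECP replicate 1, Serpina3n to -5.31 without ECP replicate 2. Also past camera were tissue-resident memory T cell (up, 4 of 9 members up, 0 down), MHC class II presentation (up, 1 of 14 up, 0 down), MHC class I presentation (up, 0 of 17 up, 0 down), immunoglobulin secretion and plasma cell (down, 1 of 13 up, 5 down) and proliferation (down, 0 of 20 up, 0 down). Their camera test gave an adjusted p = 1.37e-04 to 0.0359, and adjusted p = 0.428 to 0.760 with an estimated correlation.

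In epithelial cells, few genes passed, and named calls ended with a no-ECP library left out. The cluster led by Car1, of absorptive cells, held 38.8% and 36.1% of the class in the ECP libraries against 40.1% and 29.9%, and the goblet cell cluster with Spink4 and Muc2 23.4% and 23.6% against 31.0% and 45.6%. Of 12677 tested genes, 14 rose and 12 fell by the edgeR quasi-likelihood test. Clca4a, a chloride channel accessory protein, rose 14.1-fold (log2 3.81 ± 0.30). Gsdmc4, a gasdermin with close paralogs, rose 5.48-fold (log2 2.45 ± 0.16). Aqp4, a water channel, rose 3.05-fold (log2 1.61 ± 0.18). Slc9a3, a sodium and proton exchanger, fell 3.76-fold (log2 -1.91 ± 0.24). Dbp, a clock transcription factor, fell 4.48-fold (log2 -2.16 ± 0.27). Rbm3, a cold-induced RNA-binding protein, fell 2.86-fold (log2 -1.51 ± 0.13). Of the type I interferon list, 0 of the 19 tested members rose, 0 fell and 19 did not pass. With a median log2 fold change of 1.51, the list had a camera adjusted p = 2.61e-14 and an adjusted p = 0.865 with an estimated correlation. Alone it gave 12 up and 0 down (adjusted over the list alone). S100a8, a calcium-binding granule protein, fell 26.5-fold (log2 -4.73 ± 0.54). It also leads the neutrophil cluster, and neutrophils fell 3.99-fold in share, so their free RNA stays open. Of the neutrophil granule list, 0 of the 11 tested members rose, 1 fell and 10 did not pass. This list's camera adjusted p = 1.90e-09 became an adjusted p = 0.626 with an estimated correlation. The median log2 fold change was -0.74, and 0 rose and 5 fell adjusted over the list alone. Fkbp5 fell 2.40-fold (log2 -1.26 ± 0.12): of the glucocorticoid list, 0 of the 15 tested members rose, 1 fell and 14 did not pass. Its median log2 fold change was -0.08, with 0 up and 3 down adjusted over the list alone. By camera it had an adjusted p = 0.00509 and an adjusted p = 0.865 with an estimated correlation. The DESeq2 test called 206 genes. The 0 calls of edgeR quasi-likelihood without no_ECP replicate 2 stood beside 1564 genes at an unadjusted p under 0.05. In epithelial cells 91 genes changed without ECP replicate 1, 143 without ECP replicate 2, 10 without no_ECP replicate 1 and 0 without no_ECP replicate 2. Clca4a (3.39) and Gsdmc4 (2.67) lost their calls without no_ECP replicate 2 (log2 values). Without no_ECP replicate 1 and without replicate 2, calls ended for Aqp4 (1.5 and 1.73), Slc9a3 (-2.03 and -1.78) and Dbp (-2.01 and -2.31). The same held for Rbm3 (-1.41 and -1.62), S100a8 (-4.71 and -4.79) and Fkbp5 (-1.21 and -1.32). With a group of 1 library, a lost call does not show that 1 library makes the difference. Clca4a moved on the log2 scale to 4.41 without no_ECP replicate 1, S100a8 to -4.01 without ECP replicate 1 and -6.90 without ECP replicate 2. Another epithelial cell list past camera was T cell effector and cytotoxic (down, 0 of 11 members up and 0 down). Camera gave it an adjusted p = 0.00509, and adjusted p = 0.865 with an estimated correlation.

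In B cells, the antibody lineage, some genes of cell division and of respiration rose, as did some interferon-induced genes. A small cluster led by Ifi214 and Ifit3, both induced by interferon, held 2.12% and 0.370% of the class in the ECP libraries against 0% and 0.0822%. Of 9957 tested genes, 909 rose and 462 fell by the edgeR quasi-likelihood test; 212 of the 909 that rose were within reach of free RNA and 403 lay above the empty-droplet level in both ECP libraries. Ighg3, an IgG3 constant region, rose 32.8-fold (log2 5.03 ± 0.55) (14.3 ± 4.29 against 0.239 ± 0.338 CPM (mean ± SD, n = 2); adjusted p = 6.74e-06 by edgeR quasi-likelihood). The dividing B cell cluster held 3.91% and 3.33% of the class in the ECP libraries against 0.435% and 0.0822%. Ube2c and Ccnb2, which drive mitosis, rose 17.8-fold (log2 4.15 ± 0.31) and 31.4-fold (log2 4.97 ± 0.54): of the proliferation list, 18 of the 20 tested members rose, 0 fell and 2 did not pass. By camera the list had an adjusted p = 3.20e-39, and adjusted p = 0.711 with an estimated correlation. The members' median log2 fold change was 2.48, with 19 up and 0 down adjusted over the list alone. Ifi27l2a rose 5.49-fold (log2 2.46 ± 0.17): of the type I interferon list, 10 of the 15 tested members rose, 0 fell and 5 did not pass. For these members the median log2 fold change was 1.47, and 12 rose and 0 fell adjusted over the list alone. Tested with camera, the list had an adjusted p = 1.09e-08 and adjusted p = 0.711 with an estimated correlation. Ndufa4 and Cox6c, parts of the respiratory chain, rose 1.83-fold (log2 0.87 ± 0.13) and 1.67-fold (log2 0.74 ± 0.13): of the oxidative phosphorylation list, 14 of the 26 tested members rose, 0 fell and 12 did not pass. At a median log2 fold change of 0.41, camera gave an adjusted p = 4.31e-08, and adjusted p = 0.767 with an estimated correlation. Members up numbered 16 and members down 0 adjusted over the list alone. Egr1 rose 3.62-fold (log2 1.86 ± 0.13): of the dissociation and immediate early list, 9 of the 26 tested members rose, 0 fell and 17 did not pass. Adjusted over the list alone, 11 rose and 1 fell. Camera gave this list an adjusted p = 4.86e-06 (adjusted p = 0.767 with an estimated correlation) at a median log2 fold change of 0.17. In the same cells the colon epithelial list held 0.122% and 0.204% of the UMIs in the ECP libraries against 0.0642% and 0.0349%, and 15 of the 18 tested members rose, 0 fell and 3 did not pass. Camera's adjusted p = 9.61e-47 for this list, or adjusted p = 0.711 with an estimated correlation, and its median log2 fold change was 2.40. Of its members 16 rose and 0 fell adjusted over the list alone. The DESeq2 test called 362 genes and the largest cluster alone gave 683. In B cells 315 genes changed without ECP replicate 1 and 904 without ECP replicate 2. Ighg3 moved on the log2 scale to 8.09 without no_ECP replicate 2, Ube2c to 3.40 without no_ECP replicate 2, Ccnb2 to 6.37 without no_ECP replicate 1 and 2.51 without no_ECP replicate 2. Another B cell list past camera was tissue-resident memory T cell (up, 3 of 13 members up and 0 down). Camera gave it an adjusted p = 0.0224, and adjusted p = 0.830 with an estimated correlation.

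In T cells, Il10 and Areg rose, while most called genes were within reach of free RNA. The cluster led by Gzma held 27.2% and 51.6% of the class in the ECP libraries against 69.5% and 29.4%, and the cluster led by Foxp3 33.8% and 32.1% against 11.3% and 30.7%. Of 10070 tested genes, 43 rose and 1 fell by the edgeR quasi-likelihood test. Of the 43, 33 were within reach of free RNA. Il10, but not Areg, was among the 5 above the empty-droplet level in both ECP libraries. Klrg1, a receptor of effector and tissue regulatory T cells, rose 17.5-fold (log2 4.13 ± 0.46) (52.8 ± 10.1 against 3.16 ± 3.01 CPM (mean ± SD, n = 2); adjusted p = 0.0222 by edgeR quasi-likelihood). Il10, an inhibitory cytokine, rose 3.47-fold (log2 1.79 ± 0.24) and Areg, a growth factor of tissue repair, 5.46-fold (log2 2.45 ± 0.36): of the regulatory T cell list, 2 of the 16 tested members rose, 0 fell and 14 did not pass. The list had 7 up and 0 down adjusted over the list alone. Its camera adjusted p = 9.33e-12, or adjusted p = 0.653 with an estimated correlation, for a median log2 fold change of 0.89. Of the type I interferon list, 0 of the 18 tested members rose, 0 fell and 18 did not pass. With a median log2 fold change of 1.41, the list had a camera adjusted p = 1.09e-15 and an adjusted p = 0.653 with an estimated correlation. Alone it gave 11 up and 0 down (adjusted over the list alone). Of the Th17 and type 3 list, 0 of the 15 tested members rose, 0 fell and 15 did not pass. This list's camera adjusted p = 0.00396 became an adjusted p = 0.653 with an estimated correlation. The median log2 fold change was 0.54, and 5 rose and 0 fell adjusted over the list alone. Epithelial transcripts held 0.120% and 0.191% of the UMIs in the ECP libraries against 0.0502% and 0.0297%, and of the colon epithelial list, 11 of the 17 tested members rose, 0 fell and 6 did not pass. Its median log2 fold change was 2.45, with 16 up and 0 down adjusted over the list alone. By camera it had an adjusted p = 9.87e-85 and an adjusted p = 0.391 with an estimated correlation. Gzmb, a cytotoxic protease (-0.35 ± 0.40), Pdcd1, which encodes PD-1 (-0.21 ± 0.35), Foxp3, the regulatory T cell factor (1.15 ± 0.42), and Ifng, a cytokine (-0.45 ± 0.33), did not pass (log2 fold changes). Subtracting 5% of UMIs along the empty-droplet profile left 6 changed genes, and subtracting the share that accounts for every epithelial transcript left 0 (edgeR quasi-likelihood, 733 at an unadjusted p under 0.05). In T cells 82 genes changed without ECP replicate 1, 162 without no_ECP replicate 1 and 435 (326 up) without no_ECP replicate 2. Klrg1 moved on the log2 scale to 3.31 without no_ECP replicate 1 and 5.62 without no_ECP replicate 2, Areg to 3.19 without no_ECP replicate 2. Il10 (ENSMUSG00000016529) lies on chromosome 1, 131019845 to 131024974; Klrg1 (ENSMUSG00000030114) lies on chromosome 6, 122270596 to 122282882; Areg (ENSMUSG00000029378) lies on chromosome 5, 91139599 to 91148432. Other T cell lists past camera were T cell inhibitory receptors and exhaustion (up, 0 of 16 members up and 0 down), complement and gut resident macrophage (up, 0 of 10 members up and 0 down) and MHC class II presentation (up, 0 of 15 members up and 0 down). Their camera test gave an adjusted p = 1.10e-05 to 0.0376, and adjusted p = 0.653 to 0.776 with an estimated correlation.

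In group 2 ILC, innate lymphocytes of tissue repair, some genes of respiration and of division rose. Of 5059 tested genes, 163 rose and 63 fell by the edgeR quasi-likelihood test; 20 of the 163 that rose were within reach of free RNA and 106 lay above the empty-droplet level in both ECP libraries. Areg rose 2.61-fold (log2 1.39 ± 0.23), and Stab2, a scavenger receptor, rose 8.07-fold (log2 3.01 ± 0.39). Uqcr10 and Ndufa4, parts of the respiratory chain, rose 2.15-fold (log2 1.11 ± 0.21) and 2.12-fold (log2 1.09 ± 0.21): of the oxidative phosphorylation list, 6 of the 26 tested members rose, 0 fell and 20 did not pass. By camera the list had an adjusted p = 2.95e-10, and adjusted p = 0.265 with an estimated correlation. The members' median log2 fold change was 0.65, with 18 up and 0 down adjusted over the list alone. Top2a, a DNA topoisomerase of dividing cells, rose 5.75-fold (log2 2.52 ± 0.35): of the proliferation list, 4 of the 9 tested members rose, 0 fell and 5 did not pass. For these members the median log2 fold change was 0.78, and 5 rose and 0 fell adjusted over the list alone. Tested with camera, the list had an adjusted p = 2.22e-05 and adjusted p = 0.658 with an estimated correlation. Cxcl2, a neutrophil chemokine, rose 4.47-fold (log2 2.16 ± 0.22): of the Th17 and type 3 list, 4 of the 9 tested members rose, 0 fell and 5 did not pass. At a median log2 fold change of 0.40, camera gave an adjusted p = 7.95e-05, and adjusted p = 0.497 with an estimated correlation. Members up numbered 5 and members down 0 adjusted over the list alone. Igha and Jchain, parts of secreted IgA, fell 5.26-fold (log2 -2.39 ± 0.26) and 3.90-fold (log2 -1.97 ± 0.28), but both lay below their empty-droplet levels, which fell as well (Igha 8933 and 5083 against 33430 and 24110 CPM), so free RNA stays open: of the immunoglobulin secretion list, 0 of the 12 tested members rose, 3 fell and 9 did not pass. Adjusted over the list alone, 0 rose and 4 fell. Camera gave this list an adjusted p = 2.12e-06 (adjusted p = 0.547 with an estimated correlation) at a median log2 fold change of -0.60. Colon epithelial transcripts made up 0.102% and 0.158% of the UMIs in the ECP libraries against 0.0429% and 0.0309%, and of that list 10 of the 12 tested members rose, 0 fell and 2 did not pass. Camera's adjusted p = 1.03e-24 for this list, or adjusted p = 0.265 with an estimated correlation, and its median log2 fold change was 2.47. Of its members 11 rose and 0 fell adjusted over the list alone. Of the calls, 170 of 290 (58.6%) were up with library size alone and 45 of 54 (83.3%) with the DESeq2 test, against 72.1% with TMM. Top2a moved on the log2 scale to 3.22 without no_ECP replicate 2. Further lists past camera in group 2 ILC were T cell effector and cytotoxic (down, 1 of 11 members up and 2 down), naive and central memory T cell (down, 0 of 10 members up and 0 down), regulatory T cell (up, 1 of 10 members up and 0 down), MHC class I presentation (up, 1 of 17 members up and 0 down) and glycolysis (up, 2 of 13 members up and 0 down). Their camera test gave an adjusted p = 0.00124 to 0.0341, and adjusted p = 0.497 to 0.658 with an estimated correlation.

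In plasma cells, which secrete antibody, few genes passed and most of those that rose were within reach of free RNA. The dividing cluster with Mki67 and Top2a held 14.2% and 14.5% of the class in the ECP libraries against 8.64% and 10.7%. Of 10337 tested genes, 38 rose and 7 fell by the edgeR quasi-likelihood test; 31 of the 38 that rose were within reach of free RNA and 6 lay above the empty-droplet level in both ECP libraries. Ifi27l2a rose 10.7-fold (log2 3.42 ± 0.48): of the type I interferon list, 1 of the 9 tested members rose, 0 fell and 8 did not pass. The list had 6 up and 0 down adjusted over the list alone. Its camera adjusted p = 4.09e-11, or adjusted p = 0.934 with an estimated correlation, for a median log2 fold change of 1.13. Atf5, a stress-response transcription factor, fell 3.77-fold (log2 -1.92 ± 0.18). Asns, asparagine synthetase, fell 2.58-fold (log2 -1.37 ± 0.20). Rbm3, an RNA-binding protein, fell 2.63-fold (log2 -1.39 ± 0.16). Gpnmb, a membrane glycoprotein, fell 3.58-fold (log2 -1.84 ± 0.25). In the same cells the colon epithelial list held 0.0496% and 0.0771% of the UMIs in the ECP libraries against 0.0223% and 0.0162%, and 10 of the 18 tested members rose, 0 fell and 8 did not pass. With a median log2 fold change of 2.43, the list had a camera adjusted p = 1.92e-72 and an adjusted p = 0.581 with an estimated correlation. Alone it gave 15 up and 0 down (adjusted over the list alone). Library size alone shifted the median log2 fold change of all genes to 0.10, and subtracting 5% of UMIs along either empty-droplet profile left 0 changed genes (edgeR quasi-likelihood, with 704 and 683 at an unadjusted p under 0.05). In plasma cells 26 genes changed without ECP replicate 2, 85 (51 up) without no_ECP replicate 1 and 282 (158 up) without no_ECP replicate 2. Atf5 lost its call without ECP replicate 1 (-1.85) and ECP replicate 2 (-1.98), Asns without ECP replicate 1 (-1.30) and ECP replicate 2 (-1.44), Rbm3 without ECP replicate 1 (-1.48) and ECP replicate 2 (-1.32), Gpnmb without ECP replicate 1 (-1.87) and ECP replicate 2 (-1.82) (log2 values). Ifi27l2a moved on the log2 scale to 4.01 without ECP replicate 1 and 2.40 without ECP replicate 2. Other plasma cell lists past camera were T cell effector and cytotoxic (down, 0 of 11 members up and 1 down), MHC class II presentation (up, 0 of 15 members up and 0 down) and proliferation (up, 0 of 20 members up and 0 down). Their camera test gave an adjusted p = 0.00119 to 0.0352, and adjusted p = 0.934 to 0.988 with an estimated correlation.

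**Figure D3:**
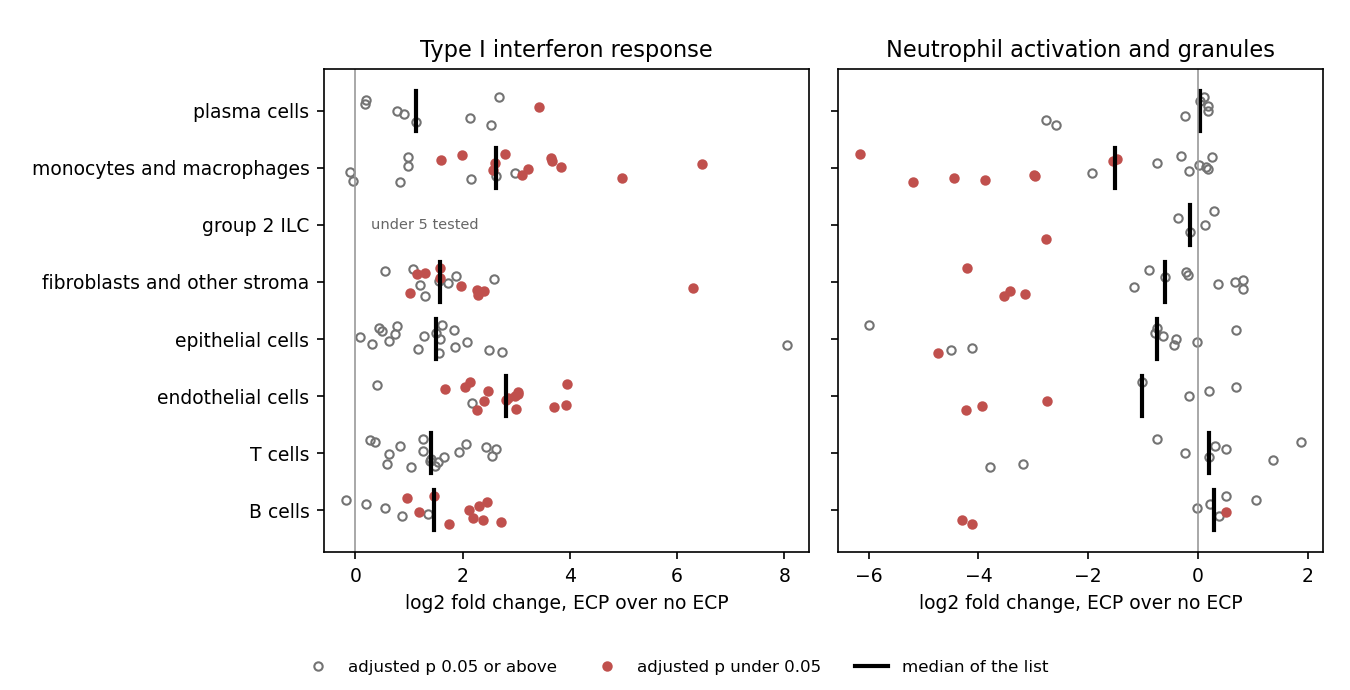
Log2 fold changes of members of the type I interferon list and the neutrophil granule list in each class. Each point is 1 gene, filled where its adjusted p is under 0.05 by edgeR quasi-likelihood.

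With all cells of a library summed, the values mix changes within classes with changes in share, and transcripts of fat cells were nearly absent from the ECP libraries. Of 17161 tested genes, 2222 rose and 921 fell by the edgeR quasi-likelihood test. Adipoq, the fat cell hormone adiponectin, fell 752-fold by the ratio of counts (95% counting interval 208 to 6216) (adjusted p = 0.00867 by edgeR quasi-likelihood), and Cfd, the fat cell protease adipsin, fell at least 9453-fold. Pdcd1 fell 2.97-fold (log2 -1.57 ± 0.19), Ifng 2.75-fold (log2 -1.46 ± 0.29) and Il6, an inflammatory cytokine, 2.10-fold (log2 -1.07 ± 0.15). Ccl5, a chemokine of cytotoxic cells, fell 5.61-fold (log2 -2.49 ± 0.18): of the T cell effector list, 0 of the 19 tested members rose, 12 fell and 7 did not pass. This list's camera adjusted p = 3.03e-06 became an adjusted p = 0.501 with an estimated correlation. The median log2 fold change was -1.35, and 1 rose and 13 fell adjusted over the list alone. Cox7b, a respiratory chain part, rose 2.68-fold (log2 1.42 ± 0.15): of the oxidative phosphorylation list, 23 of the 26 tested members rose, 0 fell and 3 did not pass. Its median log2 fold change was 0.91, with 26 up and 0 down adjusted over the list alone. By camera it had an adjusted p = 7.28e-11 and an adjusted p = 0.574 with an estimated correlation. Of the neutrophil granule list, 1 of the 20 tested members rose, 9 fell and 10 did not pass. By camera the list had an adjusted p = 1.28e-08, and adjusted p = 0.501 with an estimated correlation. The members' median log2 fold change was -1.87, with 1 up and 14 down adjusted over the list alone. Of the colon epithelial list, 18 of the 20 tested members rose, 0 fell and 2 did not pass. For these members the median log2 fold change was 2.32, and 19 rose and 0 fell adjusted over the list alone. Tested with camera, the list had an adjusted p = 2.47e-26 and adjusted p = 0.501 with an estimated correlation. For 14 genes fixed beforehand there were 77 pairs of gene and sum tested over the 8 classes above and all cells, 9 sums, of which 8 passed and 69 did not, the latter with log2 fold changes from -0.93 to 1.42. Keeping only barcodes with at most 5% mitochondrial UMIs left 2 changed genes. In all cells summed 1826 genes changed without ECP replicate 1 and 1081 without ECP replicate 2. Ifng lost its call without ECP replicate 1 (-1.16) and no_ECP replicate 1 (-1.21), Il6 without ECP replicate 1 (-0.95) and ECP replicate 2 (-1.18) (log2 values). Adipoq (ENSMUSG00000022878) lies on chromosome 16, 23146536 to 23158028.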

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

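Of the tests in this part, those of free RNA as the origin of T cell genes within its reach and of Adipoq transcription by a named class were fixed beforehand, and all others were chosen only after the result was seen. Signals outside the compared cells, each higher in both ECP libraries than in either library without ECP, were these. In empty droplets the colon epithelial list made up 1.64% and 2.29% of UMIs with ECP, against 0.987% and 0.525%. Barcodes over the mitochondrial limit were 16.9% and 21.3% with ECP, against 9.91% and 8.30%. An unnamed cluster led by Chgb and Chga, secretory proteins of hormone-producing cells, held 0.812% and 1.02% of kept cells, against 0.0358% and 0.0960%.

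Epithelial cells held a larger share of the ECP libraries. A weaker CD45 selection would raise all CD45-negative classes alike, but the log2 ratio of epithelial to fibroblast and endothelial cells was -0.31 and -0.34 with ECP and -3.33 and -3.33 without, a difference of 3.01 (SE 0.0155), which argues against it. Mitochondrial filtering as whole cause is argued against: without it the epithelial list held 1.65% and 2.15% of UMIs against 0.768% and 0.531% (ratio 2.92). A part stays open: past the filters the list held 1.35% and 1.82% against 0.454% and 0.357%. Less complete removal of the epithelial layer stays open: free epithelial RNA was higher in empty droplets (ratio 2.60). Dissection is confounded with the groups. A lining better preserved after the transplant also stays open, untested.

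Of 43 genes that rose in ECP T cells, 33 were within reach of free RNA. For the 22 of these not on the epithelial list, the rise predicted from empty droplets had a median log2 fold change of 2.41 and the rise seen one of 2.76, and the median of their differences was 0.25 (SD over genes 0.60). The limit that selects these genes also bounds how far they can exceed the prediction, so this decides nothing and free RNA stays open for them. It is argued against for 5 genes that lay above the empty-droplet level in both ECP libraries: Il10, Klrg1, Penk (an opioid peptide precursor), Tnfsf11 (a cytokine, RANK ligand) and Nckap5; with free RNA subtracted at the epithelial share 0 T cell genes passed (edgeR quasi-likelihood, 733 at an unadjusted p under 0.05), while the log2 fold changes of Il10, Klrg1 and Tnfsf11 were 1.88, 4.24 and 1.79, against 1.79, 4.13 and 1.68 before. A shift in the mix of T cell clusters as their whole cause is argued against, since 5 of the 5 also rose within the cluster led by Foxp3 (4 without ECP replicate 1, 3 without ECP replicate 2, 4 without no_ECP replicate 1 and 3 without no_ECP replicate 2); a change in the T cells, or in the mix within that cluster, stays open.

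Adipoq and other fat cell genes were found in the libraries without ECP, 96.6% of the Adipoq UMIs in an unnamed cluster led by Cfd, Car3 and Adipoq with 49 cells, and 0 cells in the ECP libraries. Named classes as the main source are argued against, since they held 3.07% of the Adipoq UMIs (41 UMIs). Transcription of Adipoq by a named class at a low level stays open: the highest level, in neutrophils, was 253% of that in empty droplets, from 7 UMIs in 1 cell, too few to decide. Fat tissue carried into the digests without ECP may account for the 49 cells, and cannot be told apart from a loss of fat cells after the transplant, since dissection is confounded with the groups.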

How the results depend on the processing

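Of the settings in this part, subtraction along the profile of barcodes with 50 to 150 UMIs or at the share set by epithelial transcripts, the largest cluster alone, and a cluster added or left out were chosen only after the result was seen, as were the neutrophil, dendritic cell and Foxp3 cluster comparisons. Over 29 results that answer a comparison there were 475 values under other settings, of which 328 held their side and size, 130 counts moved by more than 1.5 times and 17 share calls ended, and none of these changed direction, while 4 shares without a call did. Of 208 named gene calls, 3247 of 3610 values kept direction and threshold, 360 lost the threshold and 3 reversed. The cause of these shifts was not tested.

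Changed genes with the settings used throughout numbered 1371 in B cells, 44 in T cells, 506 in endothelial cells, 26 in epithelial cells, 1368 in fibroblasts and other stroma, 226 in group 2 ILC, 344 in monocytes and macrophages, 45 in plasma cells, 3143 in all cells summed, 52 in neutrophils, 61 in dendritic cells and 291 in the T cell cluster led by Foxp3.

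Counts of changed genes that moved by more than 1.5 times follow. The DESeq2 test gave 362 in B cells, 67 in T cells, 206 in epithelial cells, 897 in fibroblasts and other stroma, 54 in group 2 ILC, 78 in plasma cells, 21 in dendritic cells, 30 in the T cell cluster led by Foxp3. The largest cluster alone gave 683 in B cells, 82 in T cells, 53 in epithelial cells, 378 in fibroblasts and other stroma. At most 5% mitochondrial UMIs gave 879 in B cells, 107 in group 2 ILC, 2 in all cells summed. Resolution 0.5 gave 893 in B cells, 16 in T cells, 130 in group 2 ILC. Thinning to the lowest total gave 711 in B cells, 72 in epithelial cells, 15 in neutrophils, 14 in dendritic cells, 125 in the T cell cluster led by Foxp3. 5% of UMIs subtracted along barcodes of 1 to 50 UMIs gave 6 in T cells, 193 in monocytes and macrophages, 0 in plasma cells, 25 in neutrophils (edgeR quasi-likelihood, with 704 in plasma cells at an unadjusted p under 0.05). 5% subtracted along barcodes of 50 to 150 UMIs gave 10 in T cells, 203 in monocytes and macrophages, 0 in plasma cells, 22 in neutrophils (edgeR quasi-likelihood, with 683 in plasma cells at an unadjusted p under 0.05). Subtraction at the epithelial share gave 0 in T cells, 201 in monocytes and macrophages, 3 in plasma cells, 9 in neutrophils (edgeR quasi-likelihood, with 733 in T cells at an unadjusted p under 0.05). A minimum of 1000 UMIs gave 95 in T cells, 28 in dendritic cells. Testing with no low count filter gave 554 in T cells, 1667 in endothelial cells, 870 in epithelial cells, 2733 in fibroblasts and other stroma, 976 in monocytes and macrophages, 516 in plasma cells, 174 in neutrophils, 291 in dendritic cells. A replicate block gave 10 in T cells, 316 in epithelial cells, 87 in group 2 ILC, 69 in plasma cells, 2001 in all cells summed, 217 in dendritic cells. Adding the unnamed cluster gave 86 in T cells. Keeping doublets gave 1082 in endothelial cells, 227 in monocytes and macrophages, 34 in dendritic cells. Resolution 2 gave 828 in endothelial cells. The labels do not pair the libraries by number, and between the 2 differences taken by number the correlation across genes ranged from -0.281 to 0.0240 by sum.

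With each library left out in turn, the lone library being assumed to vary like the others, the counts of changed genes ranged from 315 to 1393 in B cells, 54 to 435 in T cells, 27 to 1458 in endothelial cells, 0 to 143 in epithelial cells, 438 to 1127 in fibroblasts and other stroma, 185 to 549 in monocytes and macrophages, 26 to 282 in plasma cells, 1081 to 3270 in all cells summed, 38 to 105 in neutrophils, 6 to 89 in dendritic cells and 124 to 427 in the T cell cluster led by Foxp3. The 0 of edgeR quasi-likelihood in epithelial cells, without no_ECP replicate 2, stood beside 1564 at an unadjusted p under 0.05.

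Lists passing camera numbered 6 in B cells, 7 in T cells, 10 in endothelial cells, 4 in epithelial cells, 10 in fibroblasts and other stroma, 10 in group 2 ILC, 12 in monocytes and macrophages, 5 in plasma cells, 13 in all cells, 10 in neutrophils, 10 in dendritic cells and 13 in the T cell cluster led by Foxp3. With an estimated correlation camera called 0 in each of these, with counts at an unadjusted p under 0.05 of 1 in B cells, 2 in T cell cluster led by Foxp3, 1 in T cells, 1 in all cells, 0 in dendritic cells, 3 in endothelial cells, 1 in epithelial cells, 1 in fibroblasts and other stroma, 2 in group 2 ILC, 2 in monocytes and macrophages, 1 in neutrophils and 1 in plasma cells. With fry, which asks whether the list as a whole moved, 2 in group 2 ILC and 1 in monocytes and macrophages passed and 0 in the others, where the counts at an unadjusted p under 0.05 were 5 in B cells, 4 in T cell cluster led by Foxp3, 3 in T cells, 9 in all cells, 2 in dendritic cells, 6 in endothelial cells, 3 in epithelial cells, 6 in fibroblasts and other stroma, 3 in neutrophils and 2 in plasma cells. Other list counts that moved were: 11 in B cells with 5% of UMIs subtracted along barcodes of 1 to 50 UMIs, 10 in B cells with subtraction at the epithelial share, 12 in B cells with the largest cluster alone, 6 in endothelial cells with the largest cluster alone, 7 in epithelial cells with the largest cluster alone, 5 in neutrophils with thinning to the lowest total, 3 in dendritic cells with thinning to the lowest total. Without each library in turn they ranged from 8 to 15 in T cells, 3 to 10 in epithelial cells, 5 to 10 in plasma cells, 5 to 12 in neutrophils, 5 to 12 in dendritic cells and 7 to 16 in the T cell cluster led by Foxp3.

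Log2 fold changes of shares, with 4 classes past the threshold, were most open to single libraries. Immune classes only gave 1 for classes with a changed share, -1.80 for neutrophils. Replicate block gave 2 for classes with a changed share, 3.04 for epithelial cells, 0.0531 for fibroblasts and other stroma, -2.19 for neutrophils. At most 5% mitochondrial UMIs gave 0.0516 for endothelial cells, -1.95 for neutrophils. TMM over the classes gave -2.35 for neutrophils. Under the replicate block dendritic cells and enteric glia passed by edgeR quasi-likelihood (adjusted p = 0.0348 each), and epithelial cells (adjusted p = 0.101) and neutrophils (adjusted p = 0.114) did not. Without each library in turn the ranges were 0 to 2 for classes with a changed share, -1.20 to 1.04 for B cells, 2.63 to 3.96 for dendritic cells, -0.33 to 0.28 for endothelial cells, 2.48 to 3.44 for enteric glia, 2.60 to 3.48 for epithelial cells, -0.44 to 0.56 for fibroblasts and other stroma, -3.38 to -1.29 for neutrophils and -0.87 to 0.0507 for plasma cells. The 0 classes of edgeR quasi-likelihood, found without ECP replicate 1 with 3 at an unadjusted p under 0.05 and without ECP replicate 2 with 2 at an unadjusted p under 0.05, are the low end of the range.

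Single genes whose log2 fold change turned direction were Iglc1 in T cells (-2.52), at 0.92 with 5% subtracted along barcodes of 50 to 150 UMIs and 0.30 with subtraction at the epithelial share, Pdcd1 in T cells (-0.21), at 0.49 with the largest cluster alone and 0.89 with resolution 0.5, Ifng in T cells (-0.45), at 0.34 with the largest cluster alone and Camp in neutrophils (at least 25.1-fold lower), at 0.97 with doublets kept. Without each library in turn the ranges were -1.04 to 0.22 for Gzmb in T cells and -0.69 to 0.45 for Pdcd1 in T cells; the cause was not tested. Not run, for want of cells, were at most 5% mitochondrial UMIs in epithelial cells, neutrophils and dendritic cells, at least 1000 UMIs and resolution 0.5 in neutrophils, and resolution 2 in neutrophils and dendritic cells. At resolution 0.5 no cluster was named dendritic cells, so that share and those genes have no value there, and the Foxp3 cluster was compared only as defined with the settings used throughout. Depth limits the number of tested genes most in neutrophils (4845) and group 2 ILC (5059), and simulated 2-fold changes were found least often in plasma cells (26.5%) and all cells summed (28.3%).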

Other observations

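All comparisons in this part, of neutrophils, dendritic cells and the T cell cluster led by Foxp3, were chosen only after the result was seen. Neutrophils had few cells, with 28 in ECP replicate 1. In neutrophils 42 of 4845 tested genes rose and 10 fell by the edgeR quasi-likelihood test; 13 of the 42 that rose were within reach of free RNA and 25 lay above the empty-droplet level in both ECP libraries. Camp, an antimicrobial granule peptide, fell at least 25.1-fold, but with doublets kept lay at a log2 fold change of 0.97 and did not pass, and Gbp2, a guanylate-binding protein, rose 9.68-fold (log2 3.27 ± 0.52). Of the neutrophil granule list, 0 of the 19 tested members rose, 3 fell and 16 did not pass. At a median log2 fold change of -0.63, camera gave an adjusted p = 2.02e-08, and adjusted p = 0.584 with an estimated correlation. Members up numbered 1 and members down 6 adjusted over the list alone. Of the interferon gamma list, 2 of the 14 tested members rose, 0 fell and 12 did not pass. Adjusted over the list alone, 9 rose and 0 fell. Camera gave this list an adjusted p = 1.52e-10 (adjusted p = 0.584 with an estimated correlation) at a median log2 fold change of 1.64. With the DESeq2 test 30 of 46 calls were up (65.2% against 80.8%). In neutrophils 105 genes changed without ECP replicate 1, 38 (8 up) without ECP replicate 2, 48 (28 up) without no_ECP replicate 1 and 91 without no_ECP replicate 2. Gbp2 lost its call without ECP replicate 2 (2.41) (log2 values). Gbp2 moved on the log2 scale to 2.46 without no_ECP replicate 1 and 3.97 without no_ECP replicate 2.

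In dendritic cells 38 of 7891 tested genes rose and 23 fell by the edgeR quasi-likelihood test; 9 of the 38 that rose were within reach of free RNA and 23 lay above the empty-droplet level in both ECP libraries. Cxcl9 rose at least 19.7-fold and Mki67, a protein of dividing cells, 2.93-fold (log2 1.55 ± 0.28): of the proliferation list, 4 of the 20 tested members rose, 0 fell and 16 did not pass. Camera's adjusted p = 1.06e-10 for this list, or adjusted p = 0.631 with an estimated correlation, and its median log2 fold change was 1.21. Of its members 11 rose and 0 fell adjusted over the list alone. Of the immunoglobulin secretion list, of which Igha and Jchain also had less free RNA in the ECP droplets, 0 of the 15 tested members rose, 5 fell and 10 did not pass. The list had 0 up and 7 down adjusted over the list alone. Its camera adjusted p = 4.29e-12, or adjusted p = 0.544 with an estimated correlation, for a median log2 fold change of -0.61. In dendritic cells 10 genes changed (4 up) without no_ECP replicate 1 and 6 (0 up) without no_ECP replicate 2. Cxcl9 lost its call without no_ECP replicate 2, Mki67 without no_ECP replicate 1 (1.41) and no_ECP replicate 2 (2.06) (log2 values).

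In the T cell cluster led by Foxp3 235 of 6834 tested genes rose and 56 fell by the edgeR quasi-likelihood test; 34 of the 235 that rose were within reach of free RNA and 138 lay above the empty-droplet level in both ECP libraries. Klrg1 rose 14.1-fold (log2 3.82 ± 0.32), Areg (log2 2.00 ± 0.20) and Il1rl1, the receptor of interleukin 33, 4.34-fold (log2 2.12 ± 0.23): of the regulatory T cell list, 3 of whose members lead the cluster, 8 of the 16 tested members rose, 0 fell and 8 did not pass. With a median log2 fold change of 0.73, the list had a camera adjusted p = 2.37e-19 and an adjusted p = 0.365 with an estimated correlation. Alone it gave 12 up and 0 down (adjusted over the list alone). Tnfrsf9, a costimulatory receptor, rose 2.68-fold (log2 1.42 ± 0.19): of the inhibitory receptor list, 6 of the 13 tested members rose, 0 fell and 7 did not pass. This list's camera adjusted p = 2.32e-09 became an adjusted p = 0.365 with an estimated correlation. The median log2 fold change was 1.03, and 9 rose and 1 fell adjusted over the list alone. Xaf1, an interferon-induced apoptosis factor, rose 4.20-fold (log2 2.07 ± 0.38): of the type I interferon list, 5 of the 8 tested members rose, 0 fell and 3 did not pass. Its median log2 fold change was 1.31, with 6 up and 0 down adjusted over the list alone. By camera it had an adjusted p = 1.95e-11 and an adjusted p = 0.365 with an estimated correlation. Of the genes fixed beforehand, 5 rose here by edgeR quasi-likelihood: Il10 (log2 1.10 ± 0.21, adjusted p = 1.32e-04), Gzmb, a cytotoxic protease (1.36 ± 0.20, adjusted p = 7.63e-07), Itgae, an integrin of tissue T cells (1.06 ± 0.24, adjusted p = 0.00235), Pdcd1, which encodes PD-1 (0.87 ± 0.27, adjusted p = 0.0450), and Foxp3, which leads the cluster (0.61 ± 0.18, adjusted p = 0.0327). The DESeq2 test called 30 genes. In the T cell cluster led by Foxp3 140 genes changed without ECP replicate 2 and 124 without no_ECP replicate 2. Il10 lost its call without ECP replicate 2 (0.64) and no_ECP replicate 2 (0.63), Gzmb without no_ECP replicate 2 (0.99), Itgae without ECP replicate 2 (0.77) and no_ECP replicate 2 (1.02), Pdcd1 without ECP replicate 1 (0.79), ECP replicate 2 (0.93), no_ECP replicate 1 (0.64) and no_ECP replicate 2 (1.31) (log2 values). Klrg1 moved on the log2 scale to 6.03 without no_ECP replicate 2, Il1rl1 to 2.99 without no_ECP replicate 2.

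Unnamed clusters held these shares: the cluster with B and T cell genes led by Satb1 and Ighd, 3.38% and 2.02% of kept cells with ECP against 7.96% and 7.59% without; the cluster led by Klrk1 and Xcl1, 2.47% and 2.32% against 2.82% and 3.87%; the cluster led by Il22 and Tnfsf11, 1.60% and 2.20% against 3.21% and 2.23%. A dividing cluster led by Hist1h1b with Gzma held 0.653% and 0.804% against 1.17% and 0.853%, one led by Il1rl1 and Dio2 0.0843% and 0.261% against 1.77% and 0.341%, and one led by Ano1 with Kit 0.0105% and 0.131% against 0.179% and 0.0107%. Only 3 splits of 4 libraries into 2 and 2 exist, too few for a share under 0.05. Splits other than the real one mix the groups, so the ECP difference enters their spread and their few calls decide nothing. Counts by the real split (highest other in parentheses) follow. B cells had 1371 (0), T cells 44 (0), endothelial cells 506 (0), epithelial cells 26 (0) and fibroblasts and other stroma 1368 (0). Group 2 ILC had 226 (1), monocytes and macrophages 344 (0), plasma cells 45 (3) and all cells 3143 (0).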
